A study of Gossypium barbadense and Gossypium hirsutum with 4 samples.

How the data were processed

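CENH3, the histone H3 variant that replaces canonical H3 in centromeric nucleosomes and marks the active centromere, was profiled in leaf tissue collected 4 weeks after planting from 2 allotetraploid cottons, Gossypium barbadense and Gossypium hirsutum. Per the labels' protocols, nuclei were digested with micrococcal nuclease (MNase), histone-DNA complexes were recovered with an antibody against CENH3, and Illumina libraries were built with a NEBNext kit. Each species had 1 ChIP library and 1 input library made without antibody, 4 libraries in all. Groups were taken from the sample titles. With 1 ChIP library per species there was no replicate error, and no difference between the species in CENH3 domains was given a p-value. The closing section tests a species difference in island density over chromosome pairs, which compares the libraries only.

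The deposited data were 2 lists of enriched regions, called islands, 1 per species. Per the submitters' processing notes, reads were handled with Trimmomatic, Bowtie2 and SICER; versions and the genome builds were not given in the sources used here. The names of the deposited lists record SICER windows of 200 bp, gaps of up to 400 bp and a false discovery rate of 0.01. They also carry the tag uniq. If it means that only uniquely placed reads were kept, repeated sequence may hold no island whatever its CENH3. The lists carry no header, and columns were read in the usual order of SICER's summary output. For each island the authors deposited the raw count of ChIP reads and the raw count of input reads, neither of them normalized. The authors' p-value and false discovery rate (a q-value) per island compare ChIP reads with scaled input reads. The authors' fold per island is a ratio of ChIP to input reads on a linear scale. These columns were checked against each other. The fold equalled ChIP over input reads times 1 constant per list, the ratio of input to ChIP library size, which was 1.64 in G. barbadense and 1.20 in G. hirsutum. Among islands with input reads and a p-value that was not extremely small, each p-value was the upper tail of a Poisson distribution whose mean was the scaled input count. The other p-values were not checked in this way. Islands with 0 input reads had been given a fold as if they held 0.25 input reads, which makes their folds very high, and 2459 islands in G. barbadense (3.64%) and 281 in G. hirsutum (0.316%) were of this kind. From the false discovery rates, the p-values and their ranks, the lists were found to be the 67639 islands kept of 101299 tested in G. barbadense and the 88971 kept of 98991 tested in G. hirsutum.

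Library totals were not used here, since the lists hold only the reads inside islands: 4068080 ChIP and 2164077 input reads in G. barbadense, and 6132203 ChIP and 3522063 input reads in G. hirsutum. These sums move with how much was called, so they are not depths. Sequence outside islands has no value in the lists and was counted as 0, which means no island was called there, not that CENH3 was absent. Both lists covered 26 chromosomes, A01 to A13 and D01 to D13, and the last island of a chromosome ended at different positions in the lists, so the coordinates belong to different assemblies. Positions are therefore given in Mb on each list's own assembly, no island was overlapped between species, and chromosomes were compared by relative position, the domain midpoint divided by the end of the last island. The end of the last island is a lower bound of the chromosome's length. A gene table for another G. barbadense assembly was at hand; its coordinates were not used, and no gene, exon or repeat annotation was assigned to any region.

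A CENH3 domain was defined before the data were examined. In bins of 100 kb, the overlap of each island with the bin was multiplied by log2 of the authors' fold (a fold below 1 set to 1), summed and divided by the bin length. Bins were smoothed with a running mean of 5 bins. The threshold was the chromosome's median plus 25% of the distance from the median to the maximum. The domain was the run of bins at or above the threshold that held the maximum, with gaps of up to 2 bins bridged. A domain was called distinct where its maximum was at least 2 times the highest smoothed bin lying more than 2 Mb outside it; other chromosomes are reported with their highest and second sites. Bin size sets the resolution of widths and positions. The ChIP to input ratio of a domain was the sum of ChIP over the sum of input reads in its islands, scaled by the library ratio, with a 95% exact binomial (Clopper-Pearson) interval. Such intervals cover counting error only, since reads without molecular identifiers are not independent molecules, and a ratio over called islands lies above the ratio of the whole interval. The arms were summarised as flanks (within 5 Mb of a domain), chromosome ends (first and last 5% of the length) and the rest, on chromosomes with a distinct domain.

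Domain width was compared between A and D homoeologues with a two-sided paired sign-flip permutation test over all sign flips, with Benjamini-Hochberg adjustment over the 2 species. Homoeologues were paired by chromosome number, and it was not checked that paired chromosomes hold the same sequence in the same order. Chromosomes are items of 1 library, so such a p describes that library and not the species. Medians over chromosomes carry an exact order-statistic interval or an interquartile range as a description. Regions to be named were fixed by rule: per species the 3 widest and 3 narrowest distinct domains, the 3 highest and 3 lowest ratios, up to 6 chromosomes without a distinct domain, the 3 largest and 3 smallest A to D width ratios, the 5 chromosomes whose relative position differed most between species, and the 5 islands outside domains with the most ChIP reads above scaled input. Other regions named in the text were chosen after their values were seen.

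The steps were tested on simulated data. When the islands of each list were placed at random on their chromosomes, no chromosome was called distinct in any of 10 runs per species. Random placement breaks up runs of weak islands, so this does not show how often such runs give a distinct call. Domains of 1.0, 1.5 and 2.0 Mb planted in 4 runs each, among other islands placed at random, were called distinct on 26 of 26 chromosomes. Their islands were drawn from each species' own distinct domains, without the low-ratio sites on D02 and D08 of G. hirsutum. The real highest sites were left out, and random placement broke up runs of weak islands here too. The planted calls and errors therefore do not show how well a domain is found against such runs. At 1.5 Mb the median error of the midpoint was 21.1 kb in G. barbadense and 30.3 kb in G. hirsutum, and the called width exceeded the planted width by a median of 200 kb in both species, which is what smoothing adds. With no planted A to D difference the sign-flip test gave a p of 0.05 or less in 3.9% of 1000 draws of 13 pairs, and with a planted difference of -0.25 Mb and an SD of 0.24 Mb it did so in 89.8%.

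Alternatives fixed before the data were examined were thresholds of 10% and 50%, bins of 50 kb, ChIP reads minus scaled input as the bin value, covered length as the bin value, a false discovery rate of 1e-10 or below, islands with a fold of at least 2 or at least 4, islands with at least 20 ChIP reads, islands without the 1% holding the most ChIP reads, no gap bridging, gaps of 10 bins, flanks of 2 Mb, covered length or percent of chromosome length in place of domain width, and the highest bin in place of the midpoint. Islands with a fold of at least 8, folds recomputed with an input of at least 3 reads, islands other than those at the first base of a chromosome, chromosomes without unmatched sites, region classes around domains called from islands of fold 4 or more, and the count of chromosomes whose highest sites lie within 5% of chromosome length in both species were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.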

Results

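The series set out to place the centromeres of G. barbadense and G. hirsutum, the cultivated cottons that each carry an A and a D subgenome of 13 chromosomes, by mapping CENH3 on their chromosomes. Each species had 1 leaf ChIP library and 1 leaf input library. The G. barbadense list held 67639 islands with 4068080 ChIP and 2164077 input reads, and the G. hirsutum list held 88971 islands with 6132203 ChIP and 3522063 input reads. Islands had a median length of 1200 bp and a total length of 102 Mb in G. barbadense, against 1800 bp and 186 Mb in G. hirsutum. The authors' fold had a median of 2.49 (interquartile range 1.87 to 4.59) in G. barbadense and of 2.17 (1.79 to 2.81) in G. hirsutum. Islands of fold 4 or more made up 28.6% of the G. barbadense list (19324 islands) and 9.75% of the G. hirsutum list (8678 islands). None of the values below has a replicate, and the intervals of ChIP to input ratios cover counting error only.

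The first question was where CENH3 lies along each chromosome, taken first in G. barbadense. A single distinct CENH3 domain stood out on each of the 26 chromosomes of this species. The domains had a median width of 1.5 Mb (interquartile range 1.4 to 1.5 Mb, range 1.1 to 1.9 Mb). Together they spanned 1.73% of the mapped chromosome length and held 43.2% of the length-weighted log2 fold of all islands. ChIP reads exceeded scaled input reads in their islands by a median of 24.2 times (range 16.7 to 33.9), and the island of highest fold on the chromosome lay inside the domain on all 26 chromosomes. With covered length as the bin value 20 chromosomes were distinct, the midpoint left the domain on 3, the share was 18% and the median ratio was 14.9 (range 1.86 to 27.5). The maximum of each domain was between 3.71 and 31.1 times the highest site elsewhere on the chromosome.

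The widest G. barbadense domains were on D08 (26 to 27.9 Mb), D10 (38.0 to 39.8 Mb) and A07 (58.6 to 60.2 Mb), with widths of 1.9, 1.8 and 1.6 Mb; A12 and D12 also reached 1.6 Mb. The narrowest was on A02 (67.2 to 68.3 Mb), at 1.1 Mb, followed by A11 (66.9 to 68.1 Mb) and D04 (27.1 to 28.3 Mb), at 1.2 Mb each. The 3 highest ChIP to input ratios were on D chromosomes. D04 reached 33.9 (95% interval 32.4 to 35.4), D03 (13.8 to 15.1 Mb) reached 33.5 (32.3 to 34.7) and D05 (42.1 to 43.5 Mb) reached 32.4 (31.1 to 33.8). The 3 lowest were on A chromosomes, at 16.7 (16.2 to 17.2) on A09 (18.4 to 19.9 Mb), 18 (17.5 to 18.5) on A02 and 19.1 (18.6 to 19.6) on A05 (55.2 to 56.5 Mb). These extremes were picked by rank, and the A and D medians were close, at 24 and 24.2. Pooled over the domains of a subgenome, the ratio was 22.5 (22.3 to 22.7) on A and 25.6 (25.4 to 25.9) on D. The A to D difference in ratio was not tested.

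Within the domains, CENH3 islands were interleaved with sequence in which no island was called. A G. barbadense domain held a median of 347 islands (range 218 to 443), which covered 43.4% of its width at the median. The longest uncovered stretch inside a domain had a median of 27.8 kb and never exceeded 62.6 kb. Domain midpoints lay between 24.2% and 71.7% of the chromosome length. By the arm ratio they gave, 17 chromosomes had a ratio of long to short arm of 1.7 or less (the metacentric class), 8 had a ratio above 1.7 and up to 3, and A09 had a ratio of 3.13.

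**Figure D1:**
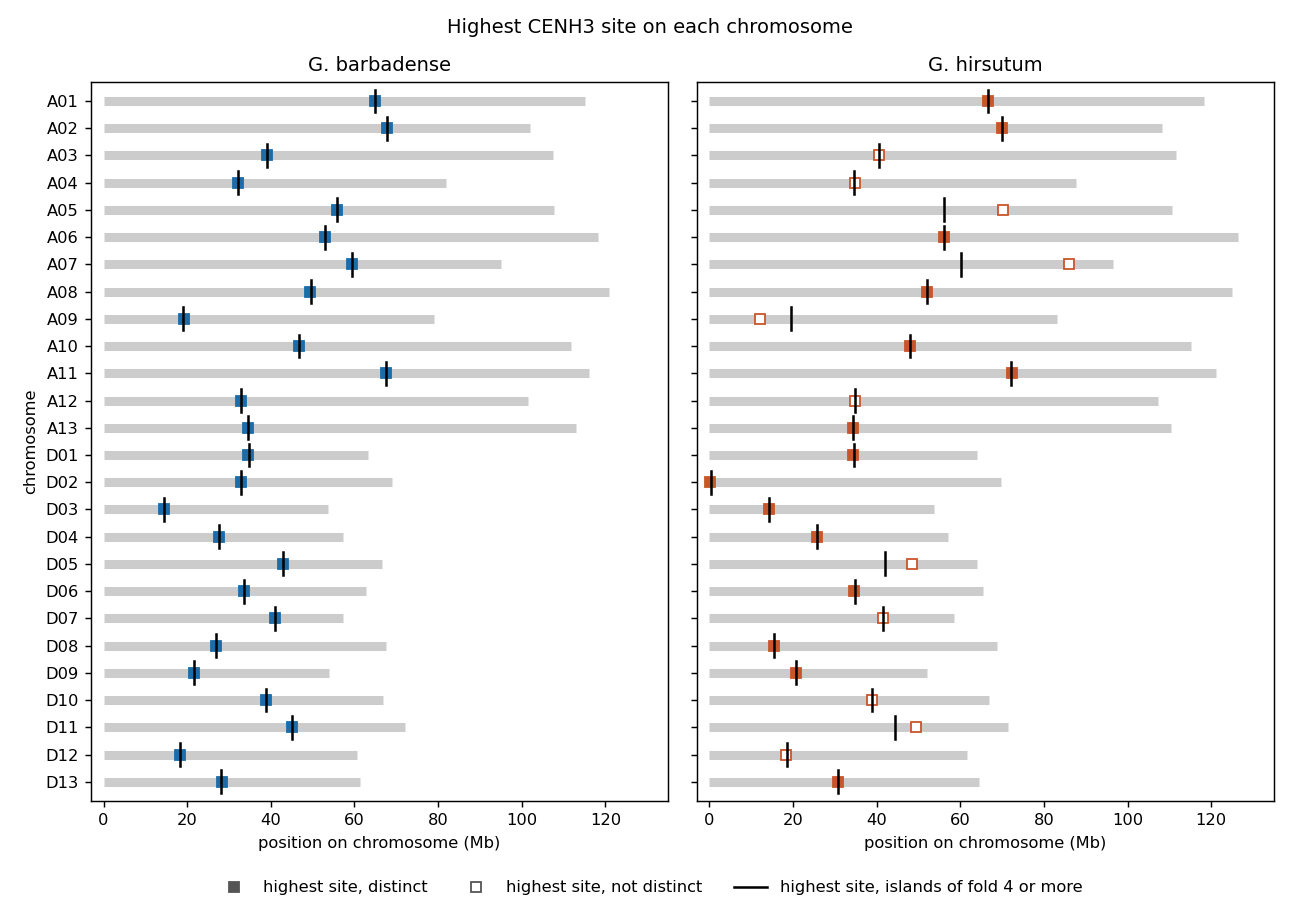
Map of the highest CENH3 site on each of the 26 chromosomes of G. barbadense (left) and G. hirsutum (right), with position in Mb on each list's own assembly; grey bars run to the end of the last island, squares mark the midpoint of the highest site from all islands (filled where distinct, open where not), and black ticks mark the midpoint from islands of fold 4 or more. Squares are filled on all 26 chromosomes in G. barbadense and on 15 in G. hirsutum, where square and tick part on A05, A07, A09, D05 and D11.

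The G. hirsutum list showed the same kind of site at lower contrast. A distinct domain was called on 15 of the 26 chromosomes, with a median width of 1.2 Mb (interquartile range 1.1 to 1.4 Mb, range 0.4 to 1.7 Mb) and a median ChIP to input ratio of 7.70 (range 1.49 to 11.2). Islands covered 15.1% of the width of these domains at the median. With ChIP minus scaled input as the bin value 9 chromosomes were distinct, and with covered length 4 were. Over the highest sites of all 26 chromosomes the median ratio was 7.43, against 2.54 and 2.32 with these bin values. The highest site of each chromosome, taken over all 26, held 6.36% of the length-weighted log2 fold. With islands of fold 4 or more alone, 22 chromosomes had a distinct domain, the exceptions being D02, D04, D08 and D11. These 22 domains had a median width of 1.15 Mb and a median ratio of 9.76 (range 7.42 to 11.1) over the islands kept, which the filter raises, and the 26 highest sites held 43.7% of the length-weighted log2 fold of the islands kept. In the same setting G. barbadense had 26 distinct domains of median width 1.4 Mb that held 73.2%.

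By the all-island rule the widest G. hirsutum domains were on A06 (55.2 to 56.9 Mb), D06 (33.8 to 35.4 Mb) and D03 (13.4 to 14.9 Mb), at 1.7, 1.6 and 1.5 Mb. The narrowest were on D02 (0 to 0.4 Mb), D08 (15.1 to 15.7 Mb) and D13 (30.2 to 31.2 Mb), at 0.4, 0.6 and 1 Mb. The highest ratios were 11.2 (95% interval 10.5 to 11.9) on A10 (47.4 to 48.5 Mb), 10.4 (9.69 to 11.2) on A01 (66.0 to 67.1 Mb) and 9.74 (9.25 to 10.3) on A08 (51.3 to 52.6 Mb). The lowest were 1.49 (1.44 to 1.54) on D02, 2.98 (2.83 to 3.13) on D08 and 3.65 (3.44 to 3.88) on D04 (24.9 to 26.3 Mb). D02 and D08 met the rule for a distinct domain and were not distinct from islands of fold 4 or more. The D02 site includes an island that starts at the first base of the chromosome, and its midpoint stayed inside the site when islands of that kind were left out, a setting added after the data were seen.

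Of the 11 G. hirsutum chromosomes without a distinct domain, the 6 with the strongest second sites were A07, A05, A09, A12, D12 and D07. On A07 the highest site (85.5 to 86.3 Mb, ratio 2.68) was only 1.07 times as high as a second one at 60.2 Mb. Around that second site, from 60 to 60.5 Mb, the ratio was 10.9 (95% interval 10.2 to 11.8). A05 and A09 were alike, with a highest site of ratio 2.83 and 2.38 and a second site of ratio 10.2 (9.49 to 11) and 10.1 (9.29 to 11). On A12, D12 and D07 the order was the other way round. Their highest sites had ratios of 9.61 (9.02 to 10.2), 7.25 (6.68 to 7.88) and 9.63 (8.69 to 10.7), and their second sites had ratios of 1.55, 2.39 and 1.63. With islands of fold 4 or more each of these 6 chromosomes had 1 distinct domain, on the site with the higher ratio.

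**Figure D2:**
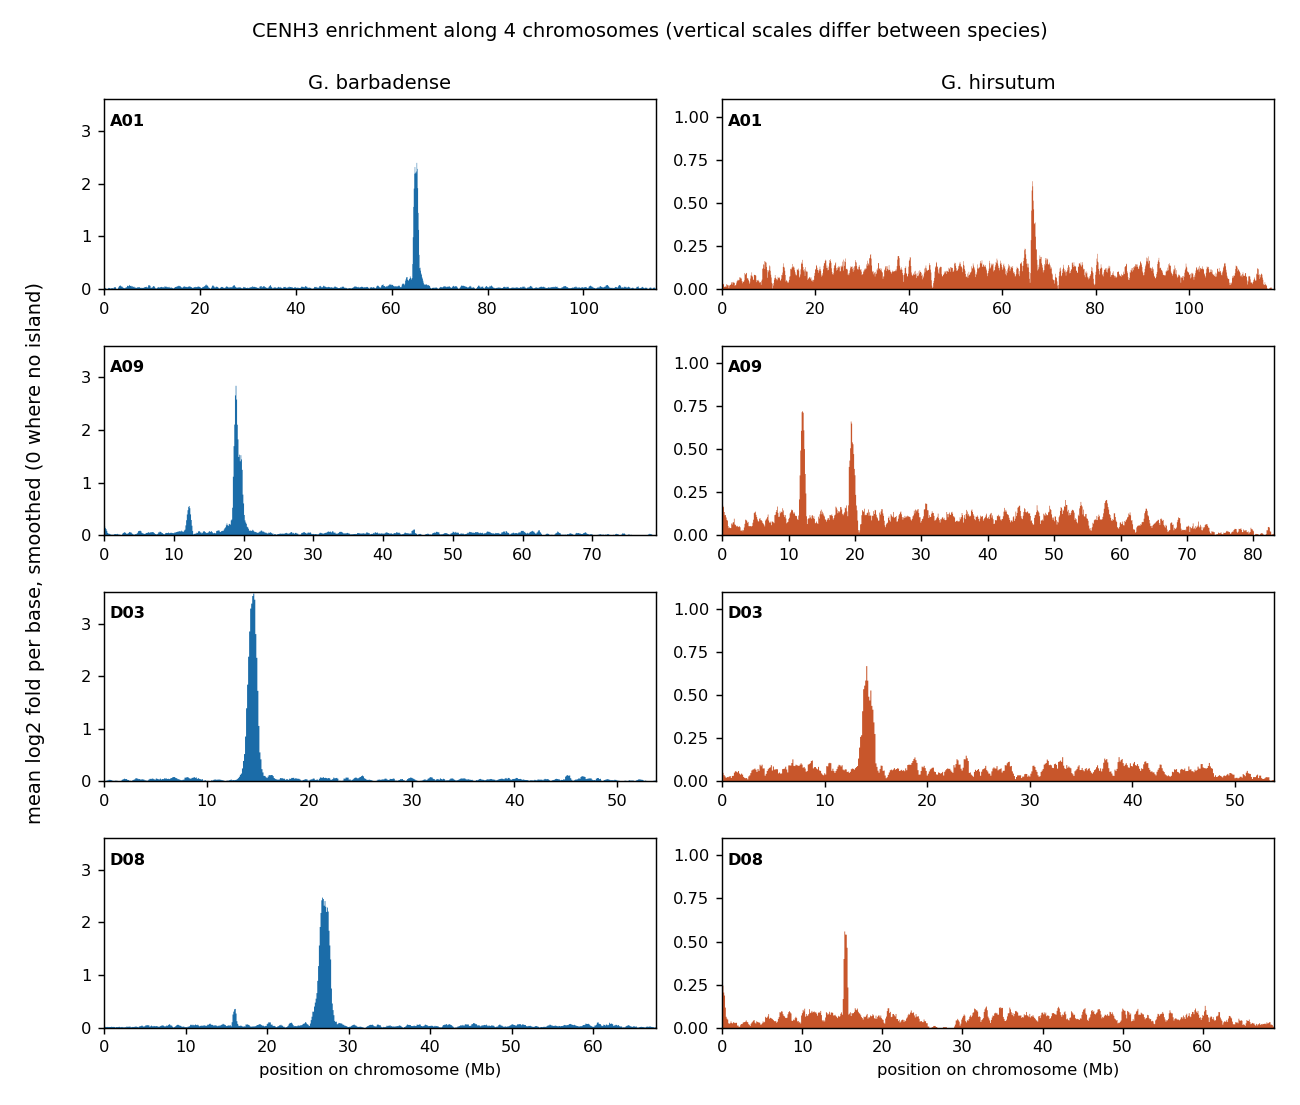
CENH3 enrichment along chromosomes A01, A09, D03 and D08 in G. barbadense (left, axis to 3.6) and G. hirsutum (right, axis to 1.1), as the mean log2 fold per base in bins of 100 kb smoothed over 5 bins (vertical axis, 0 where no island was called) against position in Mb. A09 has 2 sites in both species, of which the one near 12.1 Mb is the lower in G. barbadense and the higher in G. hirsutum; on D08 of G. hirsutum a stretch of 1.19 Mb from 26.5 to 27.7 Mb holds no island.

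The second question was how the species compare. Relative to chromosome length, the midpoints of the highest sites were on 19 of 26 chromosomes within 5% of chromosome length of each other, with a median difference of 0.513% and a largest difference of 3.33%, on D04. Over the 15 chromosomes distinct in both species the median difference was 0.690%. The 7 chromosomes beyond 5% were D02 (47.6%), A07 (26.4%), D08 (17.5%), D05 (11.6%), A05 (11.5%), A09 (9.71%) and D11 (6.67%). With islands of fold 4 or more, 24 chromosomes were within 5%, with a median difference of 0.533%, and D02 and D08 were not. With islands of fold 8 or more, a setting added after the data were seen, 25 were within 5% and D08 was the exception; the D02 site then rested on 2 islands and was not distinct. The count was lower with other bin values, at 12 of 26 with ChIP minus scaled input and 13 of 26 with covered length.

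**Figure D3:**
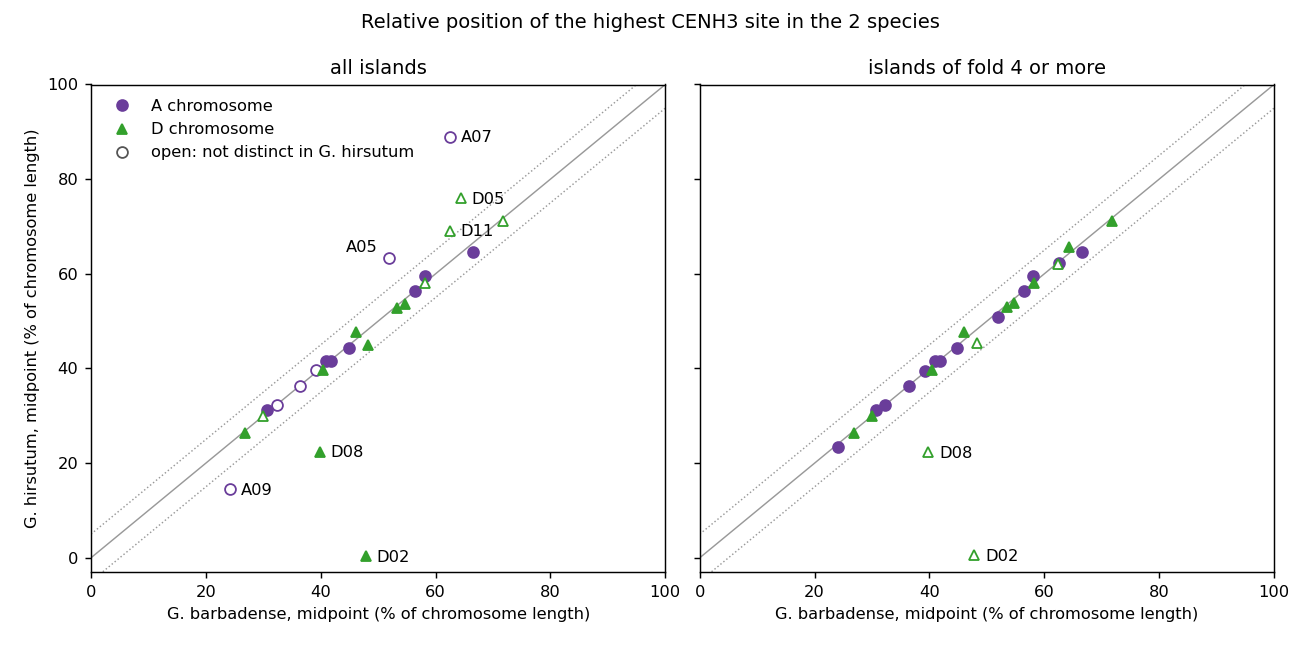
Midpoint of the highest CENH3 site as a percentage of chromosome length in G. barbadense (horizontal axis) and G. hirsutum (vertical axis), from all islands (left) and from islands of fold 4 or more (right); each point is a chromosome, open where not distinct in G. hirsutum, the solid line marks equal positions and the dotted lines a difference of 5%. Named points lie beyond 5%, 7 on the left and 2 on the right.

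Domain width showed no steady difference between the species by the all-island rule. Over the 15 chromosomes distinct in both species the median difference, G. barbadense minus G. hirsutum, was 0.2 Mb (95% order-statistic interval -0.2 to 0.4 Mb), with the G. barbadense domain wider on 9 and the G. hirsutum domain wider on 6. Without D02 and D08, whose G. hirsutum sites were unmatched (a setting added after the data were seen), the median was 0.2 Mb over 13 chromosomes, wider in G. barbadense on 7 and in G. hirsutum on 6. From islands of fold 4 or more it was 0.25 Mb (0 to 0.4 Mb) over 22 chromosomes, with 15 wider in G. barbadense, 5 wider in G. hirsutum and 2 equal. The filling of the domains differed far more than their width. Islands covered a median of 3.26 times as many bases per domain in G. barbadense over the 15 chromosomes distinct in both species by the all-island rule. These include D02 (667 against 114 kb) and D08 (740 against 173 kb), without which the median is lower. From islands of fold 4 or more it was 3.58 over 22 chromosomes, which do not include D02 and D08. The median covered length was 620 kb over the 26 G. barbadense domains and 173 kb over the 15 G. hirsutum domains, and the longest uncovered stretch in the latter had a median of 71.8 kb. The ChIP to input ratio was higher in G. barbadense on 15 of 15 chromosomes, and on 22 of 22 when only islands of fold 4 or more were counted. With 1 library per species these differences belong to the libraries, and antibody yield or depth was not separated from species.

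The third question was whether the A and D subgenomes differ. In G. barbadense, domains on the A chromosomes were 1.41 ± 0.150 Mb wide (SD over 13 chromosomes) and those on the D chromosomes 1.5 ± 0.187 Mb. Over the 13 homoeologous pairs the A minus D difference was -0.0923 Mb (SD 0.240), with A wider in 3 pairs, D wider in 6 and equal widths in 4. This difference did not pass the paired sign-flip permutation test (p = 0.230, adjusted p = 0.25). The pairs with the largest A to D width ratios were pair 4 (1.17), pair 3 (1.15) and pair 7 (1.14), and those with the smallest were pair 10 (0.722), pair 2 (0.733) and pair 8 (0.789). The A chromosomes were longer, with a median of 108 Mb against 62.8 Mb, so that the domain took a median of 1.24% of an A chromosome and 2.42% of a D chromosome. As a percentage of chromosome length the A minus D difference was -1.04 percentage points (sign-flip permutation p = 0.000244, the smallest that 13 pairs allow, adjusted p = 0.000488), with the percentage lower on A in all 13 pairs.

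Only 5 pairs were distinct on both homoeologues in G. hirsutum. Their A minus D difference was 0.36 Mb (SD 0.467), with A wider in 4 of 5 pairs (exact sign-flip permutation test p = 0.25, adjusted p = 0.25; the smallest p that 5 pairs allow is 0.0625). Its largest ratios, 3.5 in pair 2 and 2.17 in pair 8, came from the low-ratio sites on D02 and D08. Without these pairs, a setting added after the data were seen, the difference was 0.0333 Mb over 3 pairs (exact permutation p = 1; 3 pairs cannot pass). Of the others, pair 13 had 1.1, pair 6 had 1.06 and pair 1 had 0.917. From islands of fold 4 or more the difference was 0.111 Mb over 9 pairs (exact permutation p = 0.406, adjusted p = 0.406).

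**Figure D4:**
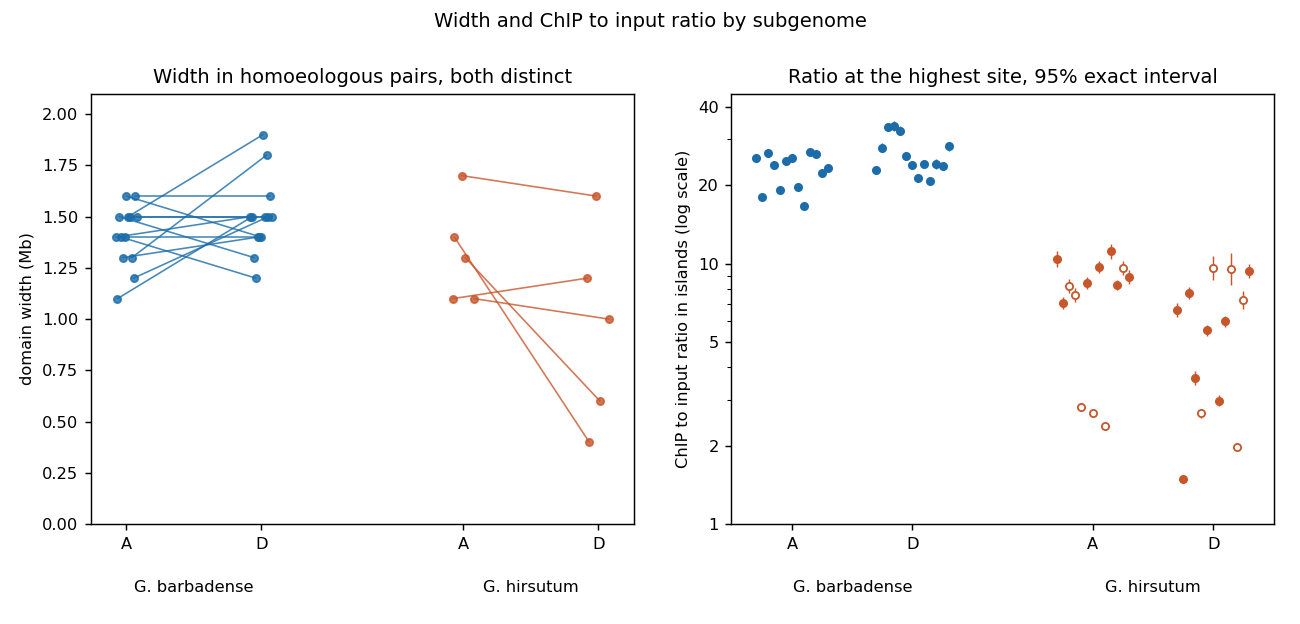
Left, CENH3 domain width in Mb on A and D chromosomes, with a line joining homoeologues that both have a distinct domain (13 pairs in G. barbadense, 5 in G. hirsutum); right, ChIP to input ratio at the highest site of each of the 26 chromosomes per species on a log axis, with 95% exact binomial intervals and open points where the site is not distinct. Ratios run from 16.7 to 33.9 in G. barbadense and from 1.49 to 11.2 in G. hirsutum.

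Enrichment was far lower outside the domains, which follows in part from their definition as the most enriched bins. In G. barbadense the median island fold was 37.2 in domains (235 islands per Mb), 2.36 in the flanks within 5 Mb (41.9 per Mb), 2.77 at chromosome ends (15.6 per Mb) and 2.23 in the rest of the arms (26.7 per Mb). In G. hirsutum, on the 15 chromosomes with a distinct domain, it was 9.48 in domains (87 islands per Mb), 2.21 in the flanks (37.9 per Mb), 2.14 at chromosome ends (19.0 per Mb) and 2.14 in the rest of the arms (42.6 per Mb). The ratio of summed ChIP to scaled input reads in the islands of the rest of the arms was 2.13 in G. barbadense (3.81% of the sequence covered) and 2.06 in G. hirsutum (8.90% covered). Of the islands of fold 8 or more, 71.3% of 11127 in G. barbadense and 61.9% of 2364 in G. hirsutum lay inside the highest site of their chromosome as found from islands of fold 4 or more, distinct or not. Those sites were chosen with the same islands, so the shares are no separate evidence for them.

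Outside the domains, the islands with the most ChIP reads above scaled input had low folds and at least 3837 input reads each. In G. barbadense they were on A09 at 44232401 to 44248600 (15269 ChIP and 12553 input reads, fold 1.99) and at 44255801 to 44265200 (fold 1.51), on D06 at 573001 to 580200 (7721 and 6278 reads, fold 2.02), on D02 at 37502601 to 37507400 (fold 1.78) and on D04 at 34504001 to 34510800 (fold 1.79). In G. hirsutum 3 of the 5 lay next to each other on A13, at 100987201 to 101000600 (27149 ChIP and 19279 input reads, fold 1.7), 101001601 to 101007200 (fold 1.55) and 101009801 to 101016800 (fold 1.54). The others were on A12 at 1 to 32600 (10150 and 9208 reads, fold 1.33) and on A03 at 68848601 to 68853600 (fold 1.57).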

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

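The 2 tests of the species difference in island density below were chosen after the densities per subgenome had been seen, as were the tests of the other 2 patterns; the tests on input reads per kb and on islands with few reads were set before their values were seen.

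The difference between A and D chromosomes in islands outside the domains was not the same in the 2 species. Outside domains and their flanks, G. hirsutum had 44.9 ± 3.02 islands per Mb on A chromosomes and 28.4 ± 2.64 on D chromosomes (SD over 13 chromosomes), and G. barbadense had 26.5 ± 1.22 and 23.5 ± 2.28. The domains left out were those from all islands in G. barbadense. In G. hirsutum they were the highest sites from islands of fold 4 or more on every chromosome, distinct or not. The log2 A to D ratio was higher in G. hirsutum by 0.49 (0.66 against 0.17), in 13 of 13 homoeologous pairs (sign-flip permutation test p = 0.00024, adjusted p = 0.00024, the smallest 13 pairs can give). For islands of fold 4 or more the difference was 1.44 (0.73 against -0.71), in 13 of 13 pairs, with the same p and adjusted p. Here the subgenomes went opposite ways, at 3.39 islands per Mb on A and 2.06 on D in G. hirsutum, and 3.79 on A and 6.22 on D in G. barbadense. Both tests compare 2 libraries over chromosome pairs, not the species over plants.

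Islands of low fold, had more of them passed at a greater depth (library totals were not used here), are not the whole of the G. hirsutum excess on A chromosomes. Among islands of fold 4 or more the A to D ratio was still 1.66 (1.55 to 1.77, mean ± 2 standard errors over pairs). A filter on fold keeps islands with few reads, and the check on read number below was run in G. barbadense only. Whether depth let more such islands pass on A chromosomes of G. hirsutum was therefore not tested. Extra genomic copies missing from the assembly are argued against only as a feature of most A islands of G. hirsutum. A median over called islands need not show such copies at a minority of them, so copies there stay open. Input reads per kb of arm island were 1.02 times as high on A as on D in G. hirsutum by medians over all islands, and the mean over pairs was 1.01 (1.004 to 1.02, ± 2 standard errors), and it was in G. barbadense, where the density of all islands (not of those of fold 4 or more) was more even, that they were 1.22 times as high. Inflated folds at islands with few reads are not the whole of the excess of strong islands on D chromosomes in G. barbadense. Among islands of 40 or more ChIP reads, with a fold of 4 or more when recomputed at an input of at least 3 reads, the A to D ratio was 0.540 (upper bound 0.631). Such islands were few, at 0.490 per Mb on A and 0.921 on D, against 3.79 and 6.22 for all islands of fold 4 or more. Most of the excess per Mb lay in islands that this check left out, and how far inflated folds account for those was not tested. A difference between the species in arm CENH3 or in background, a difference between the assemblies, and a difference between the libraries stay open, and 1 library per species does not part them.

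The highest G. hirsutum site lay away from the G. barbadense position on 7 chromosomes. A candidate explanation is that long islands of low fold outweigh the CENH3 domain in a list with weaker enrichment: with islands of fold 4 or more the highest site came back within 5% of the G. barbadense position on 5 of the 7. That the centromere has moved there is argued against, since 0 of the 7 sites had a ChIP to input ratio above the 3.65 of the weakest matched domain, and G. barbadense had its own second site, of ratio 1.85 to 2.5, within 2% of chromosome length of 6 of them, D02 being the exception. D02 and D08 did not come back at fold 4 or more, and the sequence at the expected position may be poorly represented there. The 3 Mb around it ranked at the 4.19th percentile of 3 Mb windows by islands on D02 (45 islands) and at percentile 0 on D08 (3 islands). A lack of CENH3 at that position would also leave few islands, since the lists hold only enriched sequence, so this rank cannot part the 2 readings. At fold 8 or more D02 did come within 5% (31 to 31.6 Mb), outside that window, but on 2 islands. That site was not distinct and had a ratio of 2.11 (1.93 to 2.31) over all its islands. The places of the D02 and D08 centromeres therefore stay open. So does whether the assembly lacks sequence, reads could not be placed or CENH3 is absent at the expected position.

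Islands started at the very first base on 25 of 26 chromosomes in G. barbadense and 26 of 26 in G. hirsutum. They had a median length of 16.2 and 17.2 kb and took 7.03% and 3.76% of all input reads in islands. CENH3 at the strength of the domains is argued against in these islands. Their folds were 1.04 to 1.44, against median island folds of 37.2 and 9.48 in the domains of G. barbadense and G. hirsutum. That 0 of the 51 had a fold above their list's median says little, since islands with so many reads pass at a low fold. Weaker CENH3, or CENH3 on some copies of a repeated sequence, is not excluded. A repeat at both chromosome ends stays open: 1 of 52 chromosomes had an island of 1000 or more input reads in the last 20 kb before the end of its last island, but the lists leave out sequence without ChIP excess. Reads of high-copy sequence placed at the first bases remain a candidate explanation. Input reads per kb were 20.2 times the list median in G. barbadense and 15.3 times in G. hirsutum. How this goes with the tag uniq in the list names was not tested, nor was any other biological explanation.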

How the results depend on the processing

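Settings marked as added were chosen after the data were seen. In G. barbadense 26 chromosomes stayed distinct under 12 of 13 alternatives, and midpoints stayed inside the main domain on all 26; the exception, covered length as the bin value, gave 20 distinct chromosomes and moved A05, A07 and D05. In G. hirsutum 10 of 13 alternatives gave 13 to 22 distinct chromosomes against 15; ChIP minus scaled input gave 9, covered length gave 4 and fold 8 or more (added) gave 25, D08 among them on 1 such island at its unmatched site. Matching highest sites numbered 13 to 25 under 12 alternatives against 19, and 12 with ChIP minus scaled input. G. hirsutum midpoints left the main site on 12 of 26 chromosomes with ChIP minus scaled input, 13 with covered length, 6 at fold 8, 5 at fold 4, 2 at fold 2 and 1 each at a false discovery rate of 1e-10 and without the top 1%, and on 0 under the other 6. The median ratio over 26 sites (24.2 and 7.43) ran from 14.9 with covered length to 32.8 at the 50% threshold in G. barbadense and, fold filters aside, from 2.32 with covered length to 9.18 at the 50% threshold in G. hirsutum; a filter on fold sets a floor under it (12.9 at fold 8).

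Median domain width depends on the threshold by construction: 1.8 and 1.5 Mb (G. barbadense and G. hirsutum) at 10%, 1.1 and 0.8 Mb at 50%. It was 1.3 and 1.0 Mb with ChIP minus scaled input, 2.0 and 0.75 Mb with covered length, 1.6 and just under 1.1 Mb without the top 1% of islands and 1.3 and 1.0 Mb at fold 8 or more; otherwise it stayed at 1.4 to 1.5 and 1.1 to 1.3 Mb. The median width difference between species stayed at 0.2 to 0.4 Mb and that in relative position at 0.533% to 1.59%; covered length gave 1.5 Mb and 47.7% from the 1 chromosome left.

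Stricter island filters raise the share of enrichment in domains by leaving out weak islands elsewhere. In G. barbadense and G. hirsutum it was 45.5% and 6.86% at the 10% threshold, 38.8% and 5.39% at 50%, 48.6% and 5.42% with ChIP minus scaled input, 18% and 2.52% with covered length, 68.0% and 12.9% at a false discovery rate of 1e-10, 51.5% and 9.08% at fold 2, 73.2% and 43.7% at fold 4, 87.7% and 78.0% at fold 8 (added), 36.9% and 5.13% without the top 1%, and 41.7% and 6.16% with an input of at least 3 reads (added). With at least 20 ChIP reads it was 43.6% in G. barbadense.

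The A minus D width difference stayed on its side of the threshold under 13 alternatives in each species (adjusted permutation p 0.188 to 0.961 in G. barbadense and 0.188 to 1 in G. hirsutum). In G. hirsutum 4 of these kept more than 5 pairs; with 5 or fewer the test cannot pass, and covered length as the bin value left no pair. In G. barbadense it reversed to 0.289 Mb with covered length (9 pairs, exact permutation p = 0.0625, adjusted p = 0.0625); the cause was not tested. As a percentage of chromosome length it was -1.04 points and passed (adjusted permutation p = 0.000488), because A chromosomes are longer. In G. hirsutum it reversed to -0.342 points as a percentage (5 pairs, exact permutation p = 0.375, adjusted p = 0.375), for the same reason, and to -0.5 Mb in the 1 pair left with ChIP minus scaled input. Median island folds of domains and flanks stayed inside the main interquartile range over islands with flanks of 2 Mb and with domains from islands of fold 4 or more (added). That range is a wide bound, 17.6 to 112 in G. barbadense domains, and flank width cannot change the value of domains. With domains from islands of fold 4 or more the domain medians were 38.5 in G. barbadense and 10.3 in G. hirsutum. The pairs above are chromosomes; of samples by replicate number, no paired analysis was possible because each species has 1 ChIP library.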

Other observations

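The tests on domain position and on scaling of domain width were chosen after the domains had been called.

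Secondary sites of enrichment in G. barbadense differed in strength. By smoothed enrichment the highest were on D07 at the chromosome start (0 to 0.3 Mb, ratio 1.83) and on D05 (49 to 49.5 Mb, 1.85), A09 (11.9 to 12.4 Mb, 2.1), A07 (83.8 to 84.3 Mb, 2.07) and A05 (66.2 to 66.7 Mb, 1.90), all with ratios far below the 16.7 of the weakest domain. Those on D10 (58.2 to 58.7 Mb), D06 (38.1 to 38.6 Mb) and A11 (79.7 to 80.2 Mb) had the highest ratios, at 4.10 (95% exact interval 3.55 to 4.75), 3.99 (3.75 to 4.25) and 3.37 (3.21 to 3.53). Of the 8 sites named here, those on D07, D06, A11 and D10 were also the second highest from islands of fold 4 or more, where the domain maximum was 4.48, 9.57, 13.5 and 28.3 times as high; those on D05, A09, A07 and A05 were not.

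A first hypothesis was that homoeologues share the relative position of their centromere. Across the 13 G. barbadense pairs, Pearson's r between the relative midpoints of the A and D domains was 0.669 (permutation p = 0.0134, adjusted p = 0.0403 over 3 relations) and Spearman's rho was 0.698 (permutation p = 0.0105). Without the 2 pairs whose A midpoint lay farthest from the median, r was 0.719. This goes with a shared position that may date from before the subgenomes parted, although pairs differed by up to the gap seen in pair 2, with 66.4% on A and 47.8% on D. The relation is across chromosomes of 1 library, paired by chromosome number alone.

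A second hypothesis was that domain width scales with chromosome length, and the G. barbadense data went against it between homoeologues. A chromosomes were a median of 1.67 times as long as their D partners (1.43 to 2), while the median A to D ratio of domain width was 1 (0.722 to 1.17). The width ratio lay below the length ratio in 13 of 13 pairs. This count restates the lower percentage of chromosome length on A given in the Results and is not a further test. Within subgenomes the relation of width to length did not pass the test: r was -0.209 among A chromosomes (permutation p = 0.494, adjusted p = 0.494; rho -0.284, p = 0.343; r -0.182 without the 2 chromosomes farthest from the median length) and 0.503 among D chromosomes (permutation p = 0.0773, adjusted p = 0.116; rho 0.517, p = 0.0732; r 0.513 without 2). With 13 chromosomes, a moderate relation among D chromosomes is not excluded.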
